A study of Danio rerio with 8 samples.

How the data were processed

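Total RNA of whole zebrafish embryos was hybridised to 8 Affymetrix arrays, each made from 120 embryos. The 4 groups of 2 biological replicates were wild type (WT, from crosses of the AB and TÜB strains) and MZspg at 30% epiboly (4.7 hours after fertilisation) and at 60% epiboly (7 hours). MZspg embryos lack both the maternal and the zygotic function of the spg locus, which encodes the transcription factor Pou5f3, and carry the m793 allele. The labels give no genetic background of the MZspg embryos beyond that allele. Embryos were staged after in vitro fertilisation or, from natural crosses, at the 4-cell stage, per the labels. They do not say which sample came from which route.

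The deposited values were linear signal intensities of probe sets, 1 column per array. MAS5 was used by the authors, per the submitters' processing notes, and Genedata Expressionist Analyst for their comparison of the genotypes, per the design text. In the deposited intensities all arrays had the same lowest value (1.991) and the same quantiles over their filled cells, as quantile normalisation produces. The step that did so, its settings and the rule that left cells empty are not given in the sources used here. Empty cells made up 17.3% of the table, between 14.98% and 22.42% of an array, and were concentrated in dim probe sets: 67.03% of the cells were empty in the dimmest 10% of probe sets and 0.04016% in the brightest 10%. Since each array was scaled over its own filled cells, and these numbered from 9680 to 10608, an array with fewer filled cells had lower values for the same rank. The number of arrays limits the precision of every value.

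Signals were analysed as log2(value + 9), where 9 is the 10th percentile of all values, rounded up. A fold change on this scale understates the change of dim genes. Control probe sets were left out, and a probe set was tested when at least 2 of the 8 arrays reached 41.03, the 40th percentile. Of 12477 probe sets, 30 were controls and 7375 were tested. Among the 12447 others, 9206 had 1 gene symbol in the platform annotation, 104 had several and 3137 had none. The tested probe sets covered 5219 named genes, and 9138 probe sets had a gene ID found in the current gene table. No symbol needed an update.

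Empty cells were filled with 8.345, the 10th percentile of all values, a rule chosen after the data were seen because the design had not foreseen empty cells. Among tested probe sets 1.222% of cells were filled. Where every array of a group was empty, the fold is given as a lower bound against 24.62, the 95th percentile of the signals whose replicate cell was empty. A mean that includes a filled cell is named as such.

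A model with 1 mean per group was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend; 4 residual and 7.674 prior degrees of freedom). It gave MZspg against WT at each stage, 60% against 30% epiboly in each genotype, and the interaction of genotype and stage. P-values were two-sided and were adjusted by the Benjamini-Hochberg method over the tested probe sets of a comparison. A probe set is called when its adjusted p lay under 0.05. Each ± is the SD of the 2 arrays of a group.

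Named genes followed a rule: pou5f3 always. In each genotype comparison, they were the 10 higher and 10 lower genes with the largest change among called probe sets of 1 gene whose groups did not overlap. From each gene list, up to 4 members with the smallest adjusted p were taken. By the same measure 5 higher and 5 lower genes were taken in each stage comparison, and for the interaction, where nothing passed, the 5 with the smallest p. Each gene was represented by its brightest probe set. Other called members of a list are named where a count is described, and were chosen after their values were seen.

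The 17 gene lists were tested with camera of limma on 1 probe set per gene with a preset correlation of 0.01, adjusted over the lists of a comparison. They cover SoxB1 and pluripotency-type factors, the ventral and Bmp pathway, the dorsal organizer and axial mesoderm, the Nodal pathway and endoderm, mesoderm and somite, the Fgf pathway, the Wnt pathway, neural plate and brain patterning, Hox genes, the enveloping layer and epidermis, the yolk syncytial layer with apolipoproteins and yolk processing, oocyte and maternal transcripts, germ plasm and germ cells, cell cycle and DNA replication, adhesion and gastrulation movement, p53 with apoptosis and stress, and markers of later tissues. Camera with an estimated correlation and fry were run beside it. Groups, tests, the naming rule, the lists and most alternatives were set before the data were examined.

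Spike-in controls had a geometric mean of 641.2 and 805.2 on replicate 2 of WT and of MZspg at 60% epiboly, and between 89.64 and 211.4 on the other 6 arrays, 5.41-fold less on average. These sets of arrays were treated as possible batches. Since each holds 1 WT and 1 MZspg array of 60% epiboly, the genotype difference at that stage could be taken within each batch.

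Alternatives covered the scaling between arrays, the pseudocount, the filter, the variance moderation, the arrays in the fit, the replicate number as a block, the thresholds, each array left out, the treatment of empty cells and the spike-in batches. The last 2 were added after the data were seen.

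The procedure was tested on simulated data of 7375 probe sets in which 100 changed by 2-fold and 100 by 4-fold. At 30% epiboly the genotype comparison recovered 13 and 86 of these, with 6 false among 105 calls. At 60% epiboly it recovered 18 and 87, with 10 false among 115. The stage comparison recovered 15 and 91 in WT (7 false among 113) and 12 and 87 in MZspg (3 false among 102). The interaction recovered 2 and 34 (6 false among 42). Of 16 simulated lists at 30% epiboly, the 1 that was shifted was called and 0 others were. The simulated noise was independent between genes and arrays, where the correlations estimated in the data ran from 0.0236 to 0.404 across lists. Arrays that deviate as a whole were left out too. The simulations thus cannot show how often lists or probe sets are falsely called in such data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.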

Results

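Gene expression was compared between WT and MZspg embryos at 30% epiboly and in mid-gastrulation (60% epiboly), with 2 arrays of pooled whole embryos per group. Epiboly is the spreading of the cell layers over the yolk, and the percentage states how much of the yolk they cover. Pou5f3 is a POU-domain factor of the early embryo, related to mammalian Oct4, and the comparison asks which transcripts differ when it is missing from egg and embryo. The stages lay apart on the first principal component, which held 57.29% of the variance: the 30% arrays ran from -54.17 to -26.82 and the 60% arrays from 24.12 to 69.23. WT and MZspg lay on opposite sides of 0 on the second (19.8%). Replicates correlated at 0.9212 to 0.9516 across probe sets.

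The transcript of pou5f3 itself was lower in MZspg on every array. At 30% epiboly its signal was 2850 and 3166 in WT and 1292 and 1327 in MZspg, a log2 fold change of -1.19 (SE 0.228, adjusted p = 0.0223). At 60% epiboly it was 2957 and 2214 in WT and 1268 and 890.8 in MZspg, a log2 fold change of -1.26 (adjusted p = 0.0108). The position of the probe set relative to the m793 lesion is not given, so this check of the labels is limited. Over the fits with 1 array left out, the log2 fold change stayed between -1.27 and -1.12 at 30% epiboly but did not pass without any one of the 4 arrays of that stage (highest adjusted p = 0.282). The 60% call was lost without WT replicate 1 or MZspg replicate 2 of that stage (highest adjusted p = 0.105).

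At 30% epiboly, the comparison of MZspg with WT was led by transcripts that MZspg embryos nearly lacked. The Krüppel-like factor klf17 fell from 671.8 ± 17.4 in WT to 15.3 ± 9.84 in MZspg (n = 2 each, 1 MZspg cell empty and filled), a log2 fold change of -4.87 (SE 0.365, adjusted p = 5e-05 by limma). The zinc-finger repressor snai2 fell from 543.8 ± 94.4 to 19.73 ± 3.55 (-4.26, SE 0.341, adjusted p = 6.13e-05) and the Myc family gene mych from 345.2 ± 48.9 to 21.85 ± 0.87 (-3.52, SE 0.353, adjusted p = 0.000439). The largest fall was that of the unnamed gene si:ch211-152c2.3, from 3226 ± 84.3 to 67.73 ± 60.4 (-5.67, SE 0.452). The sulfotransferase gene sult6b1 (-5.57) and the arginase gene arg2 (-3.98) fell too. The SoxC factor sox11a fell by 3.47 on its brightest probe set, and both of its other probe sets had the same direction. These 7 genes passed whichever array was left out (highest adjusted p = 0.0233, for mych). The epidermal keratin krt5 (-3.72), the Na,K-ATPase subunit atp1b1a (-3.37) and spag7 (-4.80, 1 MZspg cell empty) also fell. Their calls were lost without WT replicate 2 of 30% epiboly, and those of krt5 and atp1b1a also without WT replicate 1 (highest adjusted p = 0.117, 0.0838 and 0.0791 in that order).

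Fewer transcripts were higher in MZspg at 30% epiboly, and their changes were smaller. The kinase gene map3k14a, of the non-canonical NF-kappaB pathway, rose from 9.167 ± 1.16 (1 WT cell empty) to 257.4 ± 250 (log2 fold change 3.46, SE 0.623, adjusted p = 0.017). The calreticulin gene calr had no value on either WT array and 117.6 ± 1.23 in MZspg, at least 4.78-fold higher (adjusted p = 0.00245). The adducin gene add3a rose from 60.73 ± 0.616 to 394.2 ± 39.5 (2.53, SE 0.334, adjusted p = 0.00262), though its other probe set had the opposite sign. The remaining named genes were mid1ip1b (from 11.36 ± 3.98 to 170.2 ± 110), the neuronal stathmin stmn2a (2.64), zgc:173770 (2.32), the helicase ddx52 (2.19), the Na,K-ATPase subunit atp1a1b (2.09), the homeobox gene msx3 (2.06) and spata6l (2.04). None of these 10 calls survived leaving out WT replicate 2 of 30% epiboly, and all but calr and add3a were also lost without WT replicate 1. Some were lost without a MZspg array as well, and the highest adjusted p over the left-out arrays ran from 0.0583 for add3a to 0.373 for spata6l.

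In all, 124 of 7375 probe sets were called at 30% epiboly, 30 higher and 94 lower in MZspg, all of them by at least 2-fold. An unadjusted p under 0.05 was reached by 690 where 368.8 are expected by chance. The number of calls rested on few arrays: it was 29 without WT replicate 1, 22 without WT replicate 2 and 44 without MZspg replicate 2 of that stage. It was 31 with no filter on dim probe sets and 67 when only the 4 arrays of the stage were fitted.

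**Figure D1:**
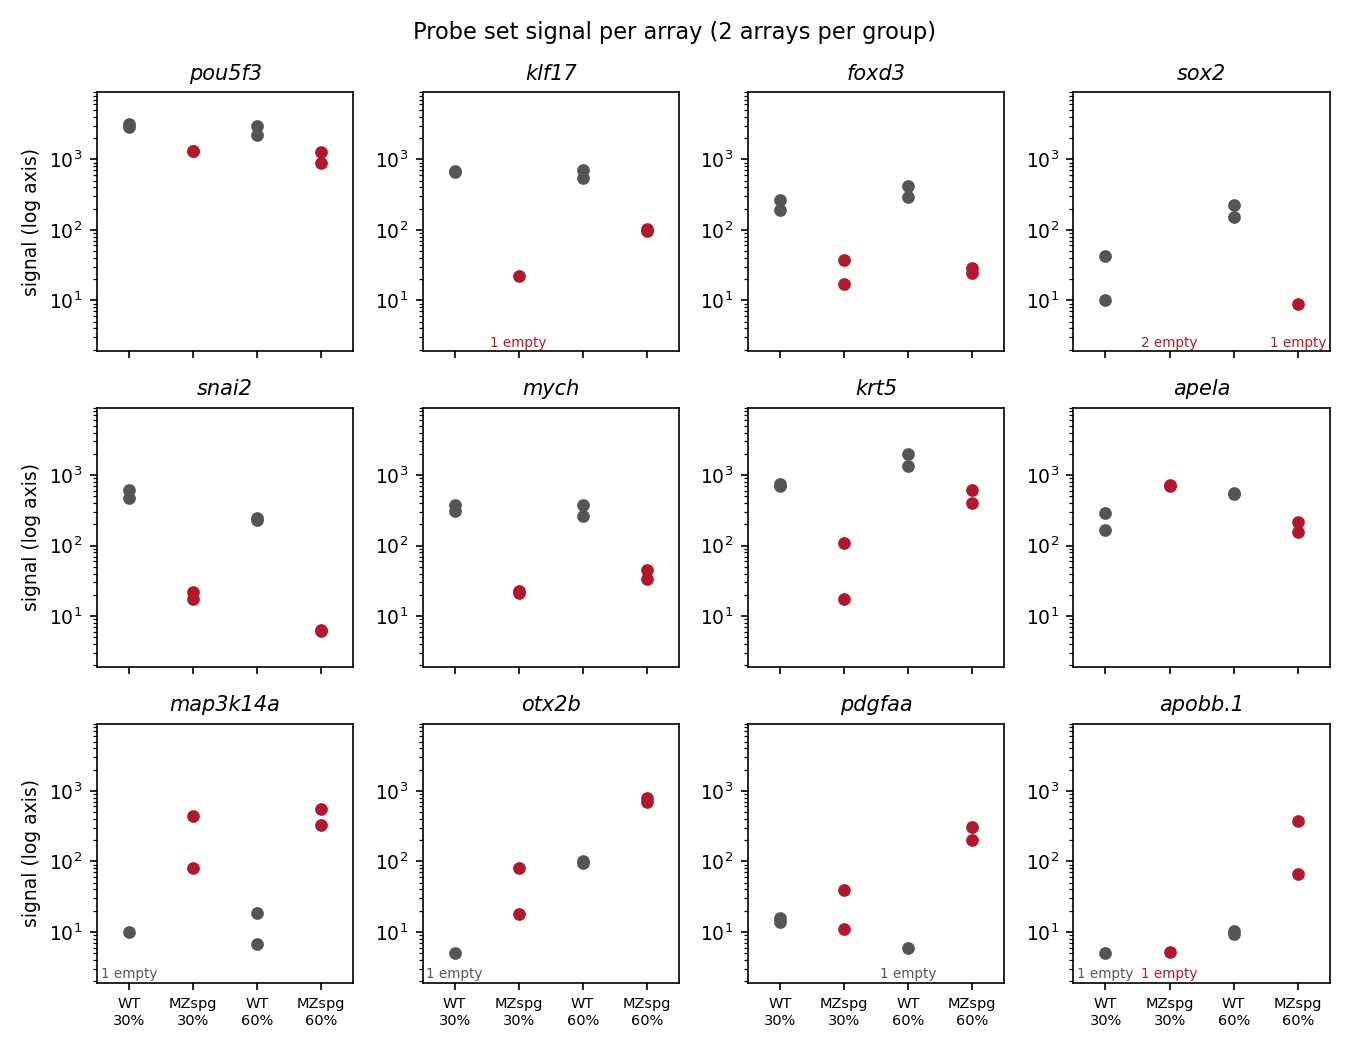
Probe set signal on each array (log axis) for 12 genes, grouped by genotype and stage, with WT in grey and MZspg in red; cells without a value are written as empty. The signal of klf17 was 671.8 on average in WT and 15.3 in MZspg at 30% epiboly, and that of otx2b was 97.97 and 751.9 at 60% epiboly.

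Among the lists, SoxB1 and pluripotency-type factors stood out at 30% epiboly. This list holds pou5f3, the gene of the mutated locus itself, and was not tested without it. Of 17 tested members 5 fell and 0 rose (6 and 0 adjusted over the list alone): klf17, mych, pou5f3, the forkhead gene foxd3 (-2.73, SE 0.398, adjusted p = 0.00513) and klf2b (-2.77, SE 0.475, adjusted p = 0.0129). Its tested SoxB1 genes were not called: sox2 (-0.854), sox3 (-0.497), sox19a (-0.909) and sox19b (-1.06; lowest adjusted p = 0.459, for sox19a). The call of foxd3 was lost without WT replicate 2 or MZspg replicate 2 of 30% epiboly (highest adjusted p = 0.116) and that of klf2b without any one array of that stage (0.205). The median of the list was -0.89, camera gave an adjusted p = 2.49e-10, and fry 0.0045, but the adjusted p = 0.123 with an estimated correlation. Of 22 genes of the enveloping layer, the outermost cell sheet, krt5 and the annexin anxa1a (-2.83, adjusted p = 0.0208) fell and 0 rose (3 fell adjusted over the list alone). The list's median was -0.41 with an adjusted p = 0.00883, and the adjusted p = 0.695 with an estimated correlation. The median was -0.64 without WT replicate 1 of 30% epiboly. The call was lost without WT replicate 2 (median -0.33, adjusted p = 0.209) or MZspg replicate 2 of 30% epiboly (-0.21, 0.296). Both called members and krt4 were lowest on the latter array, though cldnb (108.9 there, 59.9 and 82.12 in WT) was not. The MZspg signals of replicates 1 and 2 were 109.6 and 17.43 for krt5, 102.8 and 21.75 for anxa1a and 1176 and 428.2 for krt4. The call of anxa1a was lost without either WT array or MZspg replicate 2 of the stage (highest adjusted p = 0.234).

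The shift of the ventral and Bmp list at 30% epiboly was smaller, with a median of -0.33 over 22 genes (adjusted p = 0.0206, and adjusted p = 0.695 with an estimated correlation). In it msx3 rose and 0 fell (1 and 3 adjusted over the list alone). The ventral homeobox gene vox had a log2 fold change of -1.34 (adjusted p = 0.144) and the AP-2 factor tfap2a -1.15 (adjusted p = 0.153). The Fgf list had a median of -0.14 over 10 genes with 0 called (2 lower adjusted over the list alone, adjusted p = 0.0421, and adjusted p = 0.695 with an estimated correlation). Its call held in 1 of the 8 fits with an array left out, and without MZspg replicate 2 of 30% epiboly the median was 0.04 (adjusted p = 0.627). Its lowest members were etv4 (-1.42) and fgfr4 (-1.22), which did not pass. Only 2 later tissue markers were tested, of which stmn2a rose (median 1.45, adjusted p = 0.0254, and adjusted p = 0.645 with an estimated correlation). The Bmp call was lost without WT replicate 2 or MZspg replicate 2 of the stage (adjusted p = 0.209 and 0.342), and that of the later tissue markers without WT replicate 2 or MZspg replicate 1 (0.101 and 0.0811).

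The other lists were not called at 30% epiboly. Single members fell within them: sox11a and foxb1a (-2.42) of the neural list, prickle1b (-2.35), lamb1a (-2.13, 1 MZspg cell empty) and cxcr4b (-1.64) of the adhesion list, and the cyclin ccnd1 (-1.16) of 60 cell cycle genes. The apelin receptor ligand apela, a signal for mesendoderm movement, rose (1.66, SE 0.336, adjusted p = 0.0292). Each of these calls except that of sox11a was lost without WT replicate 2 of 30% epiboly and most without other arrays too (highest adjusted p from 0.138 for prickle1b to 0.446 for cxcr4b, which passed in 0 of the 8 fits). The adjusted p of these lists was 0.957 for the dorsal organizer, 0.2 for Nodal and endoderm, 0.78 for mesoderm, 0.78 for Wnt, 0.173 for neural genes, 0.402 for the yolk syncytial layer, 0.78 for oocyte transcripts, 0.724 for germ plasm, 0.277 for cell cycle, 0.113 for adhesion and 0.939 for p53 and stress. For Wnt, oocyte and adhesion genes the median was above 0 (0.05, 0.07 and 0.000336) and the mean below it (-0.05, -0.04 and -0.23). None of the 13 Hox genes on the array passed the filter.

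At 60% epiboly, several transcription factor genes were among the transcripts that fell most in MZspg. The SoxB1 factor sox2, a marker of neural and pluripotent cells, fell from 188.7 ± 51.9 in WT to 8.631 ± 0.405 in MZspg (n = 2 each, 1 MZspg cell empty), a log2 fold change of -3.46 (SE 0.457, adjusted p = 0.00182). The forkhead gene foxd3 fell from 357.9 ± 88.1 to 26.93 ± 3.16 (-3.33, SE 0.398, adjusted p = 0.00111), snai2 from 238.7 ± 15.3 to 6.228 ± 0.0468 (-4.02, SE 0.341, adjusted p = 0.000192) and the desmosomal gene pkp3a from 462.1 ± 4.44 to 43.32 ± 18.6 (-3.22, SE 0.387). The unnamed gene si:dkey-27i16.2 had no value on either MZspg array and was at least 9.23-fold lower (adjusted p = 0.00102). Lower as well were si:ch211-152c2.3 (-4.48), sult6b1 (-3.73), the actin-binding gene tagln2 (-3.49), arg2 (-3.45, 1 MZspg cell empty) and lrwd1 (-3.40). All 10 of these calls held whichever array was left out (highest adjusted p = 0.0203, for lrwd1).

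Among the transcripts higher at 60% epiboly, the growth factor gene pdgfaa rose from 7.127 ± 1.72 in WT (1 cell empty) to 252 ± 75.6 in MZspg (log2 fold change 3.99, SE 0.439, adjusted p = 0.000709). The metalloprotease gene mmp9 rose from 10.58 ± 3.16 (1 cell empty) to 205.8 ± 31.8 (3.46, SE 0.463), and the repressor zeb2a from 35.66 ± 5.43 to 472.6 ± 162 (3.39, SE 0.377). The junction gene jam3b (3.38), the lipase inhibitor angptl4 (3.12) and the apolipoprotein apobb.1 (3.18) rose too, as did map3k14a (4.38), si:dkey-51a16.9 (4.15, 1 WT cell empty), ddx52 (3.26) and add3a (3.26). All but apobb.1 passed whichever array was left out (highest adjusted p = 0.0417, for jam3b). The adjusted p of apobb.1 was 0.0546 without WT replicate 1 of 60% epiboly, and its MZspg arrays read 67.03 and 371.2.

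At this stage 333 probe sets were called, 168 higher and 165 lower in MZspg, all by at least 2-fold, and 1639 had an unadjusted p under 0.05. With the spike-in batch as a term 615 probe sets were called, including the 333, while without both high arrays 32 were. Leaving out 1 array gave 197 calls without WT replicate 1 and 194 without WT replicate 2 of 30% epiboly, 123 without WT replicate 1 and 131 without WT replicate 2 of 60% epiboly, 757 without MZspg replicate 1 and 119 without MZspg replicate 2. The balance of directions moved too: 73 were higher and 50 lower without WT replicate 1, 42 and 89 without WT replicate 2, 246 and 511 without MZspg replicate 1 of 60% epiboly, and 221 and 292 with arrays centred on their medians, and 159 of 260 were higher with no filter. The count was 513 with arrays centred on their medians, 181 with a stricter filter, 216 over probe sets with values on all 8 arrays and 65 with only the arrays of the stage.

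The SoxB1 and pluripotency-type list, again with pou5f3 among its members, was lower at 60% epiboly too, with a median of -1.40. Of 17 members 8 fell and 0 rose (12 and 0 adjusted over the list alone): sox2, foxd3, klf17 (-2.55), mych (-2.75), pou5f3 and tdgf1, the Nodal co-receptor (-1.59, adjusted p = 0.0241), and, chosen after their values were seen, nanog (-2.05, SE 0.342, adjusted p = 0.00719) and prdm14 (-2.18, 1 MZspg cell empty). Of its SoxB1 genes sox2 alone was called, while sox3 (-0.163), sox19a (-0.609) and sox19b (-1.39) were not (lowest adjusted p = 0.164, for sox19b). Camera gave an adjusted p = 1.01e-10 and fry 0.00152, with an adjusted p = 0.115 with an estimated correlation. The call of tdgf1 was lost without either WT array or MZspg replicate 2 of 60% epiboly (highest adjusted p = 0.167), and the others but pou5f3 held.

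Ventral and Bmp pathway genes moved both ways at 60% epiboly, 2 higher and 6 lower of 22 (3 and 8 adjusted over the list alone). The AP-2 factors tfap2c (-2.43, 1 MZspg cell empty) and tfap2a (-1.78) and the GATA factor gata2a (-2.05) fell, and msx3 rose (2.14). Chosen after their values were seen, the ligands bmp4 (-1.75) and bmp7a (-1.92, 1 MZspg cell empty) and the Bmp feedback gene szl (-1.34) fell, and the inhibitor smad6a rose (1.48). The median was -0.20, with an adjusted p = 0.0453 and an adjusted p = 0.52 with an estimated correlation. The list's call was lost without either WT array of 30% epiboly, WT replicate 1 or MZspg replicate 1 of 60% epiboly (highest adjusted p = 0.325), while without MZspg replicate 2 of 60% epiboly its median was -0.54 (0.00814). The Nodal and endoderm list had a median of -0.56 over 17 genes (adjusted p = 0.0103, and adjusted p = 0.41 with an estimated correlation), with tdgf1 and the chemokine receptor cxcr4b (-1.49) lower and 0 higher, also adjusted over the list alone. Its call held whichever array was left out, but the median was -0.27 without MZspg replicate 2 and -0.85 without MZspg replicate 1 of 60% epiboly. Of the genes in this paragraph, tfap2c alone passed whichever array was left out. The calls of msx3 and gata2a were lost without WT replicate 2 of 60% epiboly, and those of tfap2a, bmp4, bmp7a, szl, smad6a, tdgf1 and cxcr4b without 2 or more arrays (highest adjusted p from 0.0645 for msx3 to 0.269 for cxcr4b).

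The yolk syncytial layer list, of genes expressed at the yolk surface such as apolipoproteins, shifted upwards at 60% epiboly, with a median of 1.19 over 15 genes. In it apobb.1 and the fatty acid-binding gene fabp1b.1 rose (2.74, adjusted p = 0.0437) and 0 fell (5 and 0 adjusted over the list alone). The list's adjusted p was 0.00195, and the adjusted p = 0.41 with an estimated correlation. Its call held whichever array was left out, but the median was 0.76 without WT replicate 2, 0.81 without MZspg replicate 2 of 60% epiboly (adjusted p = 0.0249) and 0.45 without both (0.036). Some members were highest on MZspg replicate 2, though hnf4a (101.3 on replicate 1 and 78.18 on replicate 2) was not. The log2 difference from the WT array of the same number was 2.06 for replicate 1 and 4.31 for replicate 2 in apobb.1, 0.96 and 2.58 in apoa1a, and 0.31 and 3.40 in apoa2. The value of fabp1b.1 rested on 1 array: its MZspg signals were 85.75 and 688.4, and its log2 fold change was 1.30 without the higher one, MZspg replicate 2. Its call passed in 1 of the 8 fits with an array left out (highest adjusted p = 0.161). At 30% epiboly this list had a median of 0.09 and was not called.

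Lists with small downward shifts at 60% epiboly were those of cell division and maternal transcripts. Of 60 cell cycle genes the replication factors cdc6 (-1.40) and mcm2 (-1.31) fell and 0 rose, also adjusted over the list alone (median -0.24, adjusted p = 0.00585, and adjusted p = 0.41 with an estimated correlation). Of 35 oocyte and maternal transcripts mych and the junction gene jam2a (-1.60) fell (median -0.20, adjusted p = 0.0396, and adjusted p = 0.538 with an estimated correlation). Of 12 germ plasm genes nanos3, a translational repressor of germ cells, fell (-1.52; median -0.50, adjusted p = 0.0273, and adjusted p = 0.41 with an estimated correlation). For both lists the counts were the same adjusted over the list alone. Of the 2 later tissue markers stmn2a rose (2.85; median 1.75, adjusted p = 0.0273, and adjusted p = 0.41 with an estimated correlation). Over single left-out arrays the median ran from -0.37 without WT replicate 2 to -0.14 without WT replicate 1 of 60% epiboly for cell cycle genes, from -0.49 without MZspg replicate 1 to -0.09 without WT replicate 2 for oocyte transcripts, and from -0.68 without MZspg replicate 1 to -0.20 without MZspg replicate 2 for germ plasm genes. The call of the oocyte list was lost without WT replicate 2 or either MZspg array of 60% epiboly (highest adjusted p = 0.378), that of the germ plasm list without replicate 2 of either genotype (0.0818), and that of the later tissue markers without replicate 1 of either (0.0849). The calls of cdc6, mcm2, jam2a and nanos3 were lost without either WT array or MZspg replicate 2 of 60% epiboly (highest adjusted p from 0.132 for jam2a to 0.217 for nanos3), and those of mcm2 and nanos3 without further arrays.

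Neural patterning genes were not called as a list at 60% epiboly (adjusted p = 0.259). Their called members went both ways, 4 higher and 3 lower of 18 (4 and 5 adjusted over the list alone). The anterior neural gene otx2b rose from 97.97 ± 6.14 in WT to 751.9 ± 66.9 in MZspg (log2 fold change 2.83, SE 0.491, adjusted p = 0.00913). The eye and brain gene pax6a had no value on either WT array and 87.98 ± 4.27 in MZspg, at least 3.57-fold higher (adjusted p = 0.00193). The repressor her3 had no value on either MZspg array and was at least 4.26-fold lower (adjusted p = 0.00154), and foxb1a fell (-2.84). Chosen after their values were seen, her9 (2.48) and pbx4 (1.73) rose and foxi1 (-2.26) fell. The calls of pax6a, her3 and foxb1a held whichever array was left out. That of otx2b was lost without WT replicate 2 or MZspg replicate 2 of 60% epiboly (highest adjusted p = 0.0548), and those of her9, pbx4 and foxi1 without these and, for pbx4 and foxi1, further arrays (0.11, 0.205 and 0.0656).

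The remaining lists were not called at 60% epiboly. Of 17 mesoderm genes the apelin receptor aplnra (1.97), the T-box gene tbx6 (2.74, 1 WT cell empty) and the chemokine cxcl12b (2.26) rose and 0 fell (4 and 0 adjusted over the list alone). The adjusted p of the list was 0.259, and its median was -0.06 where the mean was 0.45 and the test pointed up. Of 30 adhesion genes rock2a (1.98), pcdh10b (1.94) and cxcl12b rose, and apela (-1.56), cxcr4b and, chosen after its values were seen, the hyaluronan synthase has2 (-1.54) fell (4 and 4 adjusted over the list alone; adjusted p = 0.259). In the enveloping layer list the claudin cldnf rose (2.45; adjusted p of the list 0.88, with a median of -0.17 and a mean of 0.02), and in the dorsal list otx2b rose and foxb1a fell (0.318). The adjusted p was 0.88 for Fgf, 0.72 for Wnt and 0.444 for p53 and stress, with 0 members called in each. Of the genes called in this paragraph, tbx6 and foxb1a passed whichever array was left out, aplnra and cldnf were lost without WT replicate 2 of 60% epiboly (0.0503 and 0.0751), and the rest without 2 or more arrays (highest adjusted p from 0.0548 for otx2b to 0.269 for has2 and cxcr4b).

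**Figure D2:**
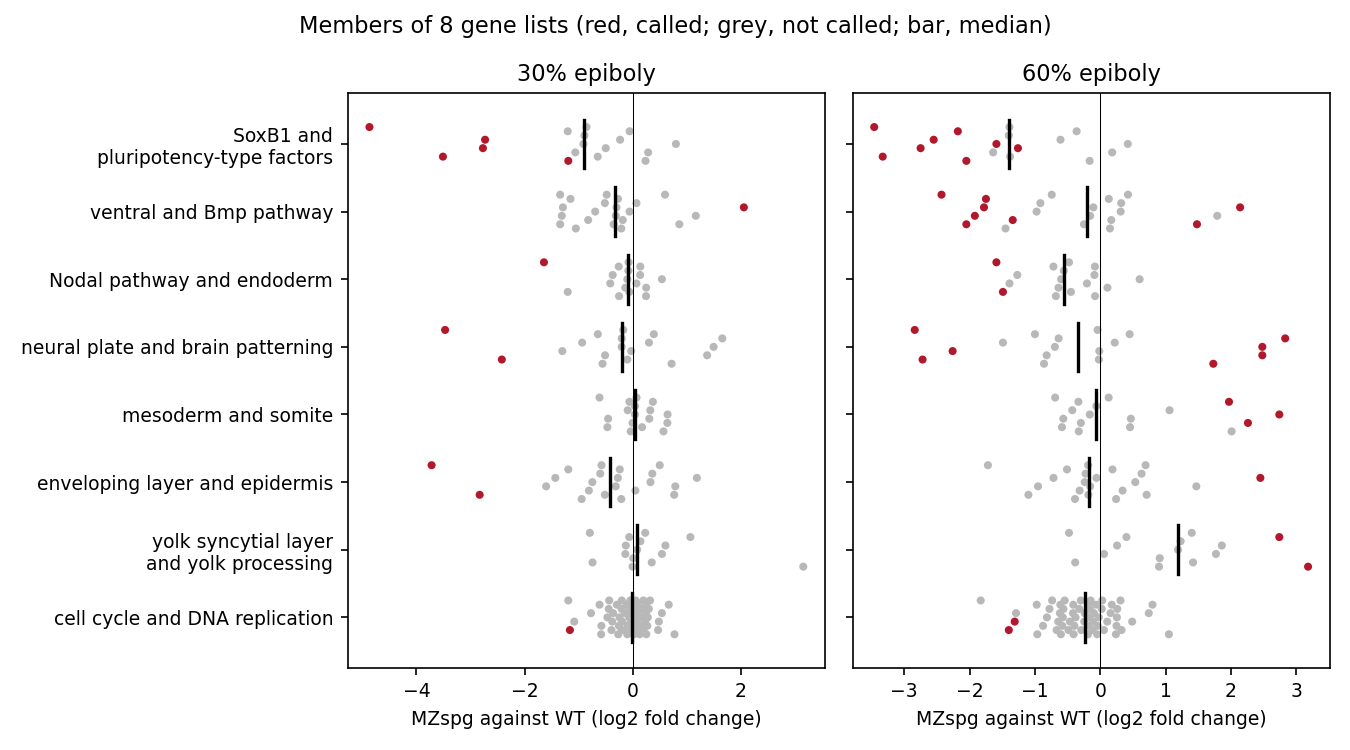
Log2 fold change of MZspg against WT (x axis) for each tested member of 8 gene lists at 30% and 60% epiboly; red points were called, grey points were not, and black bars are medians. The median of SoxB1 and pluripotency-type factors was -0.89 at 30% and -1.40 at 60% epiboly, and that of the yolk syncytial layer 0.09 and 1.19.

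The genotype differences of both stages shared many genes. At both stages klf17, snai2, mych, foxd3, arg2, sult6b1 and si:ch211-152c2.3 were lower in MZspg, and map3k14a, add3a, ddx52, stmn2a and msx3 were higher. Among all calls, 17 probe sets were higher at both stages, where 0.683 are expected of independent lists (one-sided Fisher's exact p = 4.9e-21), and 48 were lower at both, where 2.1 are expected (2.73e-56). Of the 124 calls at 30% epiboly 120 had the same sign at 60%, and 297 of 333 the other way, against 61.6% of all tested probe sets. The correlation of the log2 fold changes across probe sets, which are not independent replicates, was 0.4751. The comparisons share no array, but they share the estimated spread of each probe set, which alone can make calls coincide. Fisher's test also treats probe sets as independent, so its p-values only describe the overlap. The 1 probe set called in opposite directions was that of apela: its WT signals rose from 228.6 ± 88.5 at 30% to 554.3 ± 12.4 at 60% epiboly while its MZspg signals went from 715.3 ± 20.1 to 184.3 ± 42.2.

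**Figure D3:**
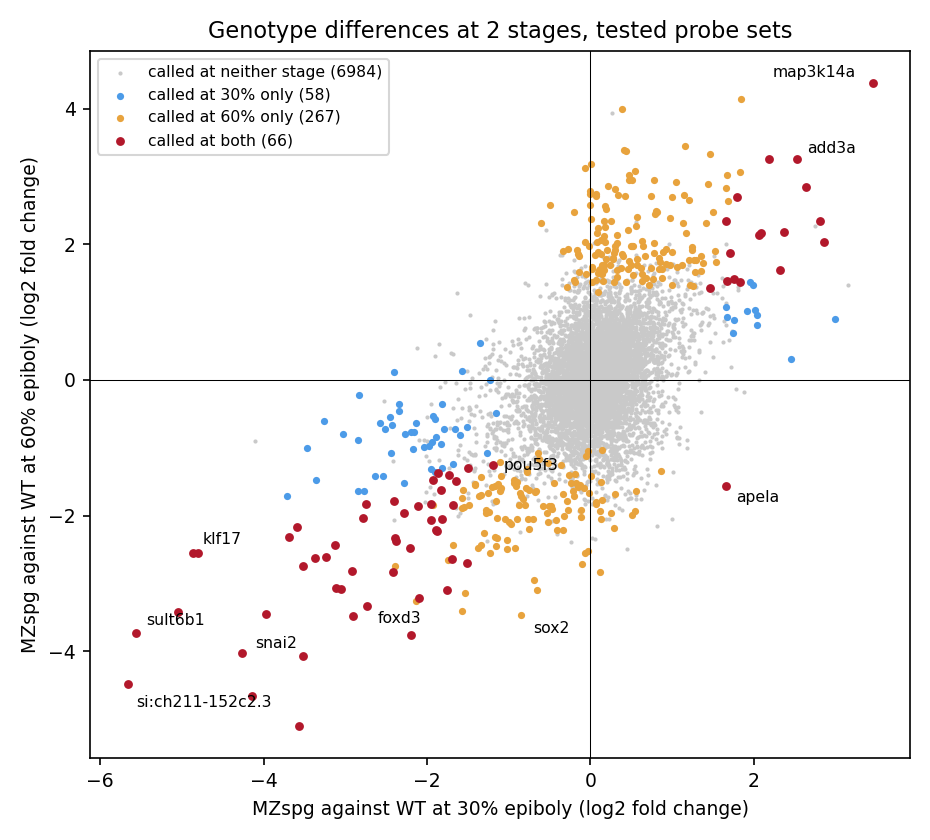
Log2 fold change of MZspg against WT at 30% epiboly (x axis) and at 60% epiboly (y axis), 1 point per tested probe set, with colours for the stage at which it was called. Of 66 probe sets called at both stages, 48 lie at the lower left, 17 at the upper right and 1, that of apela, at the lower right.

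Whether the genotype difference changed between the stages was tested as an interaction, and no single gene passed. The smallest p-values were those of apela (-3.22, SE 0.475, adjusted p = 0.101), angptl4 (3.18, SE 0.48, adjusted p = 0.101), pdgfaa (3.61, SE 0.621), pax6a (2.68, SE 0.47) and zeb2a (2.98, SE 0.532; adjusted p = 0.187 for these 3). For klf17, whose difference was -4.87 and then -2.55, the interaction was 2.32 (adjusted p = 0.315), and for sox2 -2.61 (adjusted p = 0.365). With limma 0 of 7375 probe sets passed, 638 had an unadjusted p under 0.05 where 368.8 are expected, and every other setting that kept all arrays also gave 0. Without MZspg replicate 1 of 60% epiboly 54 passed, those 5 genes among them. No more than 1 passed without any other array. Of the lists, the enveloping layer (median 0.38, adjusted p = 0.0449) and the yolk syncytial layer (median 0.58, adjusted p = 0.04) passed by camera, and both had an adjusted p = 0.696 with an estimated correlation.

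Between 30% and 60% epiboly in WT, the largest rises included genes of mesoderm and axial patterning, and the largest falls included maternal transcripts. The presomitic mesoderm factor msgn1 rose from 23.55 ± 11.6 to 687.2 ± 80.6 (log2 fold change 4.46, SE 0.685, adjusted p = 0.00629), and the caudal homeobox gene cdx4 from 55.47 ± 52.9 to 884.3 ± 126 (4.08, SE 0.597, adjusted p = 0.00582). The retinoic acid-synthesis gene aldh1a2 (3.97), bhmt (4.01) and the annexin anxa1c (3.60) rose as well. The maternal gene btg4 fell from 245 ± 178 to 23.01 ± 5.21 (-2.79, SE 0.654, adjusted p = 0.0217), and the oocyte-rich claudin cldnd from 1332 ± 281 to 205.2 ± 32.1 (-2.64, SE 0.351). The kinase prkcda (-2.76), zgc:113424 (-2.74) and zgc:56231 (-2.56) fell too. There were 1013 calls, 413 higher and 600 lower at 60% epiboly. With arrays centred on their medians 588 were higher and 547 lower, and with the spike-in batch as a term 340 were higher and 315 lower. Without WT replicate 1 of 30% epiboly limma called 0 (1262 at an unadjusted p under 0.05), so none of these 10 genes passed (highest adjusted p from 0.105 for aldh1a2 to 0.243 for btg4). Counts were 368 without WT replicate 2 of 30%, 67 without WT replicate 1 and 158 without WT replicate 2 of 60%, 211 with no filter and 655 with the spike-in batch as a term.

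Of 35 oocyte and maternal transcripts 17 fell and 0 rose in WT (median -1.24, adjusted p = 1.33e-07, and adjusted p = 0.244 with an estimated correlation), and of 12 germ plasm genes 5 fell (-0.60, adjusted p = 0.00793, and adjusted p = 0.358 with an estimated correlation). Upward shifts were those of the Bmp (median 0.91, adjusted p = 1.44e-05), yolk syncytial layer (0.96, 0.000655), mesoderm (0.91, 0.000413), dorsal organizer (0.74, 0.00355), Wnt (0.64, 0.000541), enveloping layer (0.55, 0.000921), neural (0.54, 0.00305) and adhesion lists (0.43, 0.00453). With an estimated correlation none of these 8 passed, with adjusted p from 0.244 to 0.406. Not called were the lists of SoxB1 and pluripotency-type factors (0.788), Nodal (0.788), Fgf (0.107), cell cycle (0.108), p53 and stress (0.79) and later tissue markers (0.393).

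The same direction of development was seen in MZspg, with larger changes on average, though their size depended on the MZspg arrays used. Here cdx4 rose from 12.57 ± 5.98 (1 cell empty) to 1109 ± 713 (log2 fold change 5.56, SE 0.597, adjusted p = 0.000414), bhmt from 51.45 ± 46.9 to 2277 ± 1260 (5.38, SE 0.588), and the apolipoprotein apoa1a from 18.51 ± 16.9 to 854.4 ± 524 (4.98, SE 0.518). The genes btr30 (4.90) and krt17 (4.88, 1 cell empty) rose as well. The ring-finger gene mkrn4 (-4.12, 1 cell empty), inka1a (-3.73), dctpp1 (-3.57), the Krüppel-like factor klf2a (-3.43) and cldnd (-3.25) fell. All 10 passed whichever array was left out (highest adjusted p = 0.0247, for dctpp1). The calls numbered 2405, with 1022 higher and 1383 lower, while the median of all probe sets was -0.11. They numbered 791 without MZspg replicate 2 of 30%, 1057 without MZspg replicate 2 of 60% epiboly, 1429 with only the MZspg arrays and 688 without both high spike-in arrays.

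The stage changes of the genotypes correlated at 0.7786 across probe sets without sharing an array, with an SD of 0.877 in WT and 1.15 in MZspg. Replicates also differed more in MZspg: the SD of their difference was 0.61 at 30% and 0.695 at 60% epiboly, against 0.525 and 0.533 in WT. The counts of 1013 calls in WT and 2405 in MZspg came from 1 shared estimate of spread. With only the arrays of 1 genotype fitted they were 1275 and 1429. In the shared fit, calls in both genotypes numbered 334 higher (57.2 expected of independent lists) and 460 lower (113 expected), and 1 was opposite. In MZspg 21 of 35 oocyte and maternal transcripts fell (median -1.49, adjusted p = 3.05e-07, and adjusted p = 0.287 with an estimated correlation) and 10 of 15 yolk syncytial layer genes rose while 1 fell (1.87, adjusted p = 8.03e-05, and adjusted p = 0.287 with an estimated correlation). The lists of mesoderm (1.49, 0.000101), enveloping layer (1.04, 0.000105), Bmp (0.78, 0.000722), Fgf (0.77, 0.0116), neural (0.59, 0.00842), Wnt (0.39, 0.0102) and adhesion genes (0.19, 0.0288) shifted up, and those of germ plasm (-1.17, 0.000612) and cell cycle (-0.44, 0.0169) down. With an estimated correlation their adjusted p lay between 0.287 and 0.448. Not called were the lists of the dorsal organizer (0.204), SoxB1 and pluripotency-type factors (0.675), Nodal (0.448), p53 and stress (0.684) and later tissue markers (0.246).

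Genotype differences were also set against the WT stage change. Of the probe sets lower in MZspg at 60% epiboly, 33 of 165 rose in WT between the stages, 6 fell and 126 did not pass. Of the 168 higher, 17 rose and 5 fell. Over all 7375 tested probe sets, 413 rose and 600 fell. These comparisons share WT arrays: a high WT signal at 60% epiboly lowers the genotype difference and raises the stage change. To show what sharing alone gives for the correlation and covariance, 100 simulations with no genotype difference were drawn. They did not cover the counts above. At 30% epiboly the correlation across probe sets was 0.06, where the simulations gave 0.2055, and the covariance was 0.02996 against 0.07822 (SD 0.00521), a difference of -0.04827. At 60% epiboly the correlation was 0.07 against -0.2075 and the covariance 0.04928 against -0.079 (SD 0.00492), a difference of 0.1283. The simulated noise was independent between probe sets, so the SD leaves out whole arrays that deviate along the stage axis, and no array was left out for these values.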

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

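The 3 results below were picked out because a test of the difference between the stages, or opposite calls at both, set the genotype effect at 60% epiboly apart from that at 30%. The enveloping layer list had a change in genotype difference with a median of 0.38 (camera adjusted p = 0.0449, and adjusted p = 0.696 with an estimated correlation). The yolk syncytial layer list had a median of 0.58 (adjusted p = 0.04, and adjusted p = 0.696 with an estimated correlation). For apela the difference between the stages was -3.22 (SE 0.475), which did not pass over all probe sets (adjusted p = 0.101). Its log2 fold change was 1.66 at 30% and -1.56 at 60% epiboly, and neither call held in every fit with 1 array left out. Every MZspg array lay above both WT arrays at the first stage and below both at the second, as the rule for opposite calls required.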

How the results depend on the processing

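The settings for empty cells and for the spike-in batches, the crossed pairing and the left-out arrays for lists were added after the data were seen. Calls of named genes had passed the threshold, and those of the largest changes also had groups without overlap. Their sign under other settings was thus largely fixed by the choice of genes. The 116 calls of named genes kept their sign under every setting that was run, and 33 of them stayed called in every setting that kept all arrays or left out the high spike-in pair. Leaving out 1 array gave 22 to 120 calls for MZspg against WT at 30% epiboly, 119 to 757 at 60%, 0 to 1196 for the stage change in WT, 791 to 2467 for that in MZspg, 0 to 54 for the interaction and 8 to 14 called lists, and a correlation between the stages of 0.3678 to 0.5326. In those fits the lone array of a group was assumed to vary like the arrays of the other groups. Called genes stayed past the threshold in all such fits for 7 of 32 named at 30% epiboly, 31 of 64 at 60%, 0 of 10 for the stage change in WT and 10 of 10 in MZspg. With no filter on dim probe sets 31 were called at 30% epiboly and 211 for the WT stage change, over 12447 tested. A stricter filter gave 181 at 60%, all among the 333, over 5168 tested. Fitting only the arrays compared gave 67 at 30%, 65 at 60%, 1275 for the WT stage change and 1429 for the MZspg stage change, with fewer residual degrees of freedom. Median centring gave 513 at 60% (the 333 among them), and only probe sets with all 8 values 216. The spike-in batch as a term gave 615 at 60% and 655 for the WT stage change. Without both high spike-in arrays, which leaves 1 array per genotype at 60%, the counts were 76, 32, 110 and 688 in that order of comparisons. An adjusted p under 0.10 gave 709 at 60% and 1727 for the WT stage change. List medians near 0 changed sign in some settings: that of the Fgf list at 30% epiboly, called with a median of -0.14, ran from -0.473 to 0.0415, and that of the enveloping layer at 60%, not called, from -0.414 to 0.121. Camera with an estimated correlation called 0 of 13 lists and fry 2, both the list of SoxB1 and pluripotency-type factors. Apart from the filter, the arrays in the fit and the thresholds, where the construction shows it, the cause was not tested. The labels' replicate numbers share no stated batch, and deviations of equal numbers correlated at -0.143 at 30% and 0.078 at 60% epiboly. With the replicate block the calls were 113, 301, 825, 2203 and 0, and 13 lists; crossing the numbers at 30% epiboly gave 117 and 378. Lists with cells left empty were not run, because camera needs complete values. Dim signals limit what can be told: 1.222% of tested cells were empty.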

Other observations

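The gene families below, and the tests on developmental age and on spike-in batches, were chosen after the results were seen. The families were picked for their called members, so no test of a family as a whole is given. Of 7 keratins, the filaments of the outer cell layers, at 30% epiboly krt5 (-3.72), krt97 (-2.85, from 1548 ± 282 to 303.2 ± 321) and krt99 (-2.43, 1 MZspg cell empty) fell and 0 rose, also with quantile normalisation and median centring. The other members did not pass, such as krt4 (-1.43), krt8 (-0.81) and krt18a.1 (0.05). At 60% epiboly 0 were called, and the interaction of krt5 was 2.00 (adjusted p = 0.533). The 3 calls were lost without either WT array of 30% epiboly, and those of krt97 and krt99 also without MZspg replicate 2 (highest adjusted p = 0.117, 0.318 and 0.238). The fall was deepest on that array: the MZspg signals of replicates 1 and 2 were 109.6 and 17.43 for krt5 and 530.3 and 76.09 for krt97.

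Other families split. Of 5 Na,K-ATPase subunits, the pump that sets sodium and potassium gradients, the catalytic atp1a1b was higher in MZspg at both stages (2.09 and 2.17) and the accessory atp1b1a lower (-3.37 and -2.62, with its other probe set at -2.38 and -2.38). The calls of both at 30% epiboly were lost without either WT array of that stage (highest adjusted p = 0.166 and 0.0838), and that of atp1b1a at 60% without WT replicate 2 (0.0646). Among 10 hairy and Hey-type repressors at 60% epiboly, her9 (2.48), her2 (at least 2.18-fold higher) and hey1 (1.70) rose and her3 fell. The calls of her9, her2 and hey1 were lost without WT replicate 2 or MZspg replicate 2 of 60% epiboly (highest adjusted p = 0.11, 0.0794 and 0.128). Of 6 T-box factors tbx2b (2.95) and tbx6 (2.74) rose at 60% epiboly whichever array was left out, while the mesoderm factors tbxta (-0.43) and tbx16 (-0.16) did not pass. These directions were the same with quantile normalisation and median centring. Of 9 claudins cldnf rose, and of 32 SR-protein and hnRNP splicing factors srsf1a (-1.90), srsf7a (-1.59) and hnrnpa0a (-1.16) fell at 60% epiboly, where quantile normalisation and median centring each added 1 higher member. These 3 calls were lost without WT replicate 2 or MZspg replicate 2 of 60% epiboly (highest adjusted p = 0.0917, 0.229 and 0.299).

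The genes called in the same direction at both stages may differ because Pou5f3 is missing, which is the design's own contrast, or because embryos differed in age or in strain. An age difference was not decided. Of 65 such calls 28 (43.1%) had the sign of the WT stage change, where older or younger embryos would give mostly one sense. Most of these signs may be noise: of the calls at 30% epiboly, 74 of 94 lower and 25 of 30 higher ones had no called WT stage change. The calls also share WT arrays with the stage change. Genes that change only before 30% epiboly are not covered by it. A strain variant under a probe set stays open. Of 10 other tested probe sets of the same genes, 7 had the called sign at both stages (70%, Clopper-Pearson 34.8 to 93.3%), with 5 of 6 for genes lower in MZspg and 2 of 4 for genes higher. The interval treats them as independent, though they came from 8 genes. A shared sign could be a value near 0: only 2 of the 10 were called at 30% and 2 at 60% epiboly. The median ratio of their log2 fold change to the called one was 0.498 for genes lower and 0.136 for genes higher. Strain differences in expression itself were not tested, since the background of the MZspg embryos is not given.

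The larger stage change in MZspg may come from 1 array rather than from the genotype. The slope of the MZspg stage change on that of WT was 1.254 on average, and over the 4 pairs of single MZspg arrays it was lowest, 0.9324, for replicate 1 of both stages and highest, 1.575, for replicate 2 of both. A MZspg array out of stage thus stays open. It stays open too for groups of genes whose WT signals were mostly higher at 60% epiboly and whose median or called members leaned on MZspg replicate 2: the enveloping layer and the called keratins at 30% epiboly, and the yolk syncytial layer at 60%. As the sole cause, 1 WT array out of stage is argued against, since the slope of WT on MZspg was at most 0.7696 over the WT pairs. The slope was taken against the mean MZspg stage change, which a MZspg array out of stage could enlarge. It thus cannot exclude a WT array out of stage beside a MZspg one. On the first principal component the MZspg replicates 1 and 2 lay furthest apart, at -26.82 and -54.17 at 30% and at 43.2 and 69.23 at 60% epiboly. The WT replicates lay closer together, at -46.68 and -35.61 at 30% and at 24.12 and 26.72 at 60% epiboly. A true difference in the pace of development stays open too and was not tested apart from an array out of stage. A batch stays open as well, since both arrays with high spike-in controls were of 60% epiboly. Batch was thus partly confounded with stage in both genotypes. With the batch as a term the stage calls were 655 in WT and 1701 in MZspg, against 1013 and 2405 without it.

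A batch of arrays, marked by high spike-in controls in replicate 2 of both genotypes at 60% epiboly, might have made the differences of that stage. It is argued against as the whole cause: of 124 probe sets called at 30% epiboly, where no array had high controls, 116 had the same sign in both 60% pairs. Independent signs would give 31. That background is too low, since 4964 of all 7375 tested probe sets had 1 sign in both pairs. Over all probe sets the differences within the pairs correlated at 0.569. Each batch held 1 array of each genotype at 60% epiboly, so a shift shared by its arrays cancels in the 60% difference. For the same reason the batch as a term could not change that difference, only its estimated spread. That all 333 calls remained with it, among 615, is thus no evidence against a batch. Without both high arrays 31 of the 333 were left, with 1 array per genotype. In the remaining pair the median log2 difference was 1.68 for the 168 higher and -1.87 for the 165 lower calls, over probe sets chosen by these same arrays. A batch effect that differed between the genotypes was not tested for calls made at 60% alone.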
